A study of Musa acuminata AAA Group with 4 samples.

How the data were processed

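Transcript levels were measured by RNA sequencing in Cavendish banana (Musa acuminata, AAA Group, a triploid clone) sampled after 60 days in sand on a complete nutrient solution or on a low-nitrogen solution. The 4 libraries were 1 from leaf and 1 from root under each solution, so each group had 1 library. Per the labels' protocols, poly(A) RNA was fragmented and copied with random hexamers, and no step that marks the strand is stated. The submitters' processing notes name BWA and Bowtie, without role or version. The counting tool, the genome build, the annotation and the test behind the deposited comparisons are not given in the sources used here.

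For each library the authors deposited, per the file headers, an expected count per gene (an estimated number of fragments, which need not be whole) and an FPKM value (fragments per kilobase of gene, scaled to library size). A gene with no fragments was left out of a library's list and was read here as 0. The expected counts summed to 4164782 in normal-N leaf, 4144048 in low-N leaf, 4393407 in normal-N root and 4408992 in low-N root. Of the 31873 genes seen in any library, 93.6% had a length divisible by 3. The length used was therefore taken to be a coding length without untranslated regions, which was not checked against an annotation.

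The authors also deposited, for each tissue, a filtered table of low N over normal N with a log2 ratio, a p-value and an FDR. The log2 ratios in the authors' deposited tables were at least 1.00 in size, and the highest FDR was 0.000997 in both tissues. The lowest FPKM in those tables was 0.001, where the library's own list had no value for the gene. Those p-values compare a library with a library, not a condition with a condition, and they were not used as tests here. Gene descriptions came from those tables alone (best BLAST match and KEGG orthology text), so 3396 genes had an entry to take a description from, and 2713 of them had an informative one. None of the gene IDs (0 of 31873) matched the reference gene table of the assembly Baxijiao, so no coordinates are given.

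Changes were expressed as log2 of (FPKM + 1) in low N over (FPKM + 1) in normal N, a scale that understates the change of weakly expressed genes. A gene counted as higher or lower by size when that value was at least 1 in size and the higher library had at least 2 FPKM. With 1 library per group there was no replicate check, no test was run, and no p-value was computed. Folds of single genes are ratios of expected counts, rounded to whole numbers and scaled by library totals, with exact 95% Clopper-Pearson intervals. Intervals cover counting error only, not the spread between plants. Where a library had 0 counts, the fold was bounded with a floor of 3 counts in that library, which corresponds to 0.680 to 0.724 FPKM for a 1 kb gene. The bound leaves out the counting error of the other library, so it is not the lower end of a 95% interval.

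Before the data were examined, 42 gene lists were fixed as search terms on the descriptions, with the rule for naming genes. A list's median log2 change, over members with a mean of at least 1 FPKM, was placed as a percentile among 10000 random lists of the same size, drawn from all genes of either filtered table and matched on mean expression in 20 bins. Lists with fewer than 5 such members have values only. Because descriptions were taken only from the filtered tables, every list holds genes that the authors' filter had picked in these libraries, and its count is not independent evidence of its direction. The genes of those tables with a mean of at least 1 FPKM had a median log2 change of 1.02 in leaf (2828 genes) and -0.12 in root (3142 genes), which is what a random list resembles. Each random list mixed genes picked in leaf with genes picked in root. A list with more genes picked in the tissue at hand can reach an extreme percentile for that reason alone. Percentiles are therefore descriptions and not independent evidence of a direction either. Some search terms caught genes outside the list's name through the KEGG text, so each list was also drawn from the BLAST description alone, an alternative chosen after seeing the data.

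Named genes were, in each tissue, the 8 most positive and 8 most negative changes among genes of the filtered table with an informative description and at least 10 FPKM in the higher library. Added to them were up to 2 members per direction of each list with at least 5 FPKM, and the most abundant described member for the main steps of nitrogen uptake and assimilation. For the comparison of tissues, 5 genes per direction with opposite calls and at least 10 FPKM were taken, and for leaf against root 5 genes per direction. Asparagine synthetase and glutamate dehydrogenase were also on that list of steps, but no described gene carried either name.

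Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 10 FPKM, a size limit of 2, and scaling by median ratios, by total FPKM or by the upper quartile. Lists were also taken with members of at least 5 FPKM, without a filter on members and with the mean in place of the median. The calling rule was tested on simulated counts for 31873 genes. The changed genes were drawn from those with a mean of at least 10 FPKM, so recovery of weaker genes was not measured. A factor of 2 equals the size limit of the rule, so incomplete calling there was built in. In the leaf simulation 44.8% of 67 genes changed by a factor of 2 were called, and all of those changed by 4 or 8, with no wrong direction. In the root simulation 46.3% of 67 genes changed by a factor of 2 were called, and likewise all at 4 and 8. Of 100 unchanged lists of 20 genes, 2 in the leaf simulation and 3 in the root simulation lay outside the central 95% of random lists. Those lists were drawn from 21335 and 24151 simulated genes, not from the smaller, filtered set used for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.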

Results

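Transcript levels were compared between low-nitrogen and normal-nitrogen banana plants after 60 days, separately in leaf and in root. The 4 libraries held 4144048 to 4408992 expected fragments on genes, with 26796 genes detected in normal-N leaf, 26951 in low-N leaf, 29158 in normal-N root and 29130 in low-N root. The tissues were sampled as an aboveground part, which per the series' design text comprised leaves and pseudostems, and as roots. Each group had 1 library, so none of the differences below has a replicate check, and the intervals given with folds cover counting error only.

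The question in leaf was which transcripts differed after growth on the low-nitrogen solution. Photosystem and antenna transcripts were lower in low-N leaf, and NRT2 and NAR2 genes of nitrate uptake (4 of 4 measured) and ammonium transporters (2 of 3 measured) were higher by size. In the authors' deposited table for leaf, 35 photosystem and antenna genes were lower and 0 were higher. The aboveground samples held pseudostem as well as leaf, and for these genes too a different share of pseudostem in each library was not tested. The small chain of RuBisCO, the carbon-fixing enzyme (Ma02_g24600), took the largest share of counts in both leaf libraries and was at 47042 FPKM in normal-N leaf and 19671 FPKM in low-N leaf, 2.40-fold lower (95% interval 2.37 to 2.42). Ammonium transporter 3 member 1-like (Ma05_g28430) was at 7.22 and 109 FPKM, 15.1-fold higher under low N (11.1 to 21.0).

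The photosystem and antenna list had a median log2 change of -1.44 over 36 measured members, below all 10000 matched random lists, and 34 of 36 were lower by size. Like every list here it holds only genes that the authors' filter had picked for change in leaf or root. Among them, a chlorophyll a-b binding protein of the LHCII type 1 (Ma05_g08930) was at 34.6 FPKM under normal N and 1.26 FPKM under low N. The most abundant antenna gene by mean level among these picked genes, also of LHCII type 1 (Ma04_g07920), was at 1259 and 595 FPKM, 2.12-fold lower (2.01 to 2.24). Calvin cycle genes had a median of -1.23 over 6 members, at percentile 2.20, with chloroplast glyceraldehyde-3-phosphate dehydrogenase A (Ma06_g17760) at 156 and 49.6 FPKM. The chlorophyll synthesis list had a median of -1.26 over 6 members, at percentile 2.45. By BLAST description alone, which leaves out genes found through the KEGG text, the median was -1.43 over 5 members, at percentile 1.725. A protochlorophyllide reductase gene of that list (Ma03_g14780) was at 9.92 and 0.41 FPKM. Of the chlorophyll breakdown and senescence genes in the authors' deposited table, 3 were higher and 2 lower in leaf. STAY-GREEN (Ma07_g18910), a protein of chlorophyll breakdown, was at 11.5 and 73.2 FPKM, 6.29-fold higher (4.46 to 9.12). Pheophorbide a oxygenase (Ma04_g31690) was at 71.8 and 171 FPKM. Starch and sucrose genes, 1 higher and 7 lower in the authors' deposited table, had a median of -1.13 over 11 members at percentile 1.77 and a mean of -0.64. The large subunit of glucose-1-phosphate adenylyltransferase (Ma06_g28940), an enzyme of starch synthesis, was 5.12-fold lower (3.53 to 7.63).

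Of the NPF family, which carries nitrate and other small solutes, 10 genes were higher and 1 lower in the authors' deposited table for leaf. The median of its 12 measured members, 1.22, stood at percentile 78.4, which is inside the range of random lists. NPF 6.2-like (Ma07_g08280) was at 3.57 and 62.5 FPKM, 17.5-fold higher (11.8 to 27.0), and NPF 3.1 (Ma05_g26750) was at 11.6 and 0.41 FPKM. All 4 members of the high-affinity NRT2 transporters and their partner NAR2 in the authors' deposited table for leaf were higher. NRT2.3-like (Ma04_g06400) was at 18.4 and 119 FPKM, 6.46-fold higher (5.32 to 7.92). Amino acid and oligopeptide transporters were higher for 14 genes and lower for 0 in the authors' deposited table, with a median of 1.35 at percentile 94.9, also inside the central 95% of random lists. The amino acid permease BAT1 homolog (Ma00_g04010) was at 4.46 and 44.3 FPKM, and vacuolar amino acid transporter 1 (Ma06_g08530) at 18.1 and 152 FPKM. An isoaspartyl peptidase/L-asparaginase (Ma08_g19880) was 4.47-fold higher (3.49 to 5.79). The nitrogen assimilation list had 2 genes higher and 4 lower in leaf in the authors' deposited table. By BLAST description alone it had 1 higher and 3 lower there. Its median was then -0.22 over 8 measured members, at percentile 20.1, inside the central 95% of random lists. Nitrate reductase (Ma09_g14900) was at 1052 and 906 FPKM and nitrite reductase (Ma09_g14720) at 348 and 374 FPKM, while the chloroplast glutamine synthetase leaf isozyme (Ma09_g16600) was at 85.9 and 24.7 FPKM, 3.48-fold lower (2.86 to 4.26).

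WRKY transcription factors, many of which act in stress and senescence, were higher in leaf for 49 genes and lower for 0 in the authors' deposited table. Their median log2 change of 1.90 over 51 members exceeded all 10000 random lists, but 49 genes of the list had been picked for change in leaf. WRKY31 (Ma10_g15390) was at 69.8 and 533 FPKM, 7.62-fold higher (6.93 to 8.38), and a WRKY17 gene (Ma09_g23420) at 5.82 and 52.6 FPKM. NAC factors had a median of 1.34 at percentile 97.5, with 22 genes higher and 3 lower in the authors' deposited table. NAC68-like (Ma05_g07350) was at 13.6 and 89.4 FPKM, and NAC21/22-like (Ma11_g21100) at 17.6 and 1.55 FPKM. The ethylene list had 31 genes higher and 2 lower in the authors' deposited table, with a median of 1.26 at percentile 97.2, inside the central 95% of random lists. Most of its members were transcription factors described as ethylene-responsive, matched on that family name, rather than genes of ethylene synthesis or perception. By BLAST description alone the ethylene list had 27 higher and 1 lower in the authors' deposited table and stood at percentile 99.175, outside the central 95%. The gibberellin list, at percentile 99.6, held mostly scarecrow-like and carboxylesterase genes found through the KEGG text; drawn from BLAST descriptions alone it stood at percentile 89.65, with 7 higher and 0 lower in the authors' deposited table. The gibberellin receptor GID1C-like (Ma06_g17630) was at 7.48 and 71.6 FPKM. The cytokinin list, 5 higher and 10 lower in the authors' deposited table, had a median of -1.16 at percentile 0.070 and a mean of -0.61. It also held other genes through the KEGG text, such as LUX-like and APL-like transcription factors. By BLAST description alone it had 3 higher and 5 lower in the authors' deposited table. It then stood at percentile 4.345, inside the central 95% of random lists. The response regulator ARR8-like (Ma03_g08570) was 6.47-fold lower (3.66 to 12.3). The ribosomal list, with 12 higher and 17 lower in the authors' deposited table, stood at percentile 0.40 with quartiles of -1.36 and 1.23 and a mean of -0.12, but it also held WAT1-related and receptor kinase genes through the KEGG text. By BLAST description alone it had 1 gene higher and 13 lower in the authors' deposited table and stood at percentile 0.60.

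Among single genes, in a list or not, the most positive leaf change of a described gene was in a primary amine oxidase (Ma01_g13020), at 8.94 and 263 FPKM, 29.3-fold higher (23.5 to 37.0). Sulfate transporter 3.5 (Ma03_g21470) was at 1.93 and 64.6 FPKM, and exostosin-2 (Ma07_g14770) at 3.68 and 59.5 FPKM. An early nodulin-like protein (Ma06_g20300) and the zinc finger protein ZAT11-like (Ma09_g03190) had 0 counts in normal-N leaf. By the floor of 3 counts they were at least 6.83-fold and 6.70-fold higher. A cyclin-dependent kinase regulatory subunit 1 gene (Ma02_g13600) was at 0 and 12.9 FPKM, but its copy of equal coding length (Ma02_g13560) was at 47.2 and 12.9 FPKM and both had equal values in the other libraries, so their levels are uncertain. The most negative was ribonuclease 3-like (Ma09_g07590), at 267 and 0.61 FPKM, 441-fold lower (122 to 3645). Linoleate 9S-lipoxygenases, which oxidise fatty acids, were at 170 and 1.26 FPKM (Ma06_g26850) and at 73.7 and 1.39 FPKM (Ma06_g26840). A Bowman-Birk proteinase inhibitor (Ma04_g24980) was at 48.1 and 0.82 FPKM. A mannose/glucose-specific lectin (Ma09_g10470) was at 34.1 and 0 FPKM, at least 19.0-fold lower by the floor of 3 counts. A non-specific lipid-transfer protein (Ma04_g17220) was at 653 and 23.8 FPKM. SPX domain protein 1-like (Ma10_g26920), of the phosphate-sensing SPX family, was at 252 and 13.0 FPKM, 19.5-fold lower (14.5 to 26.7). WD repeat-containing protein 76 (Ma01_g14260) was at 32.3 and 0 FPKM, at least 4.98-fold lower by the floor of 3 counts.

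By size alone, 2537 genes were higher and 1454 lower in low-N leaf among 21715 genes at the filter. That balance depended on the scaling: 63.6% of the called genes were higher with FPKM as deposited and 46.5% after median-ratio scaling (1938 higher, 2234 lower), a scaling that moved the median log2 change of all genes from 0.12 to -0.08. Simulated counting noise alone gave a mean of 371 higher and 368 lower genes.

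**Figure D1:**
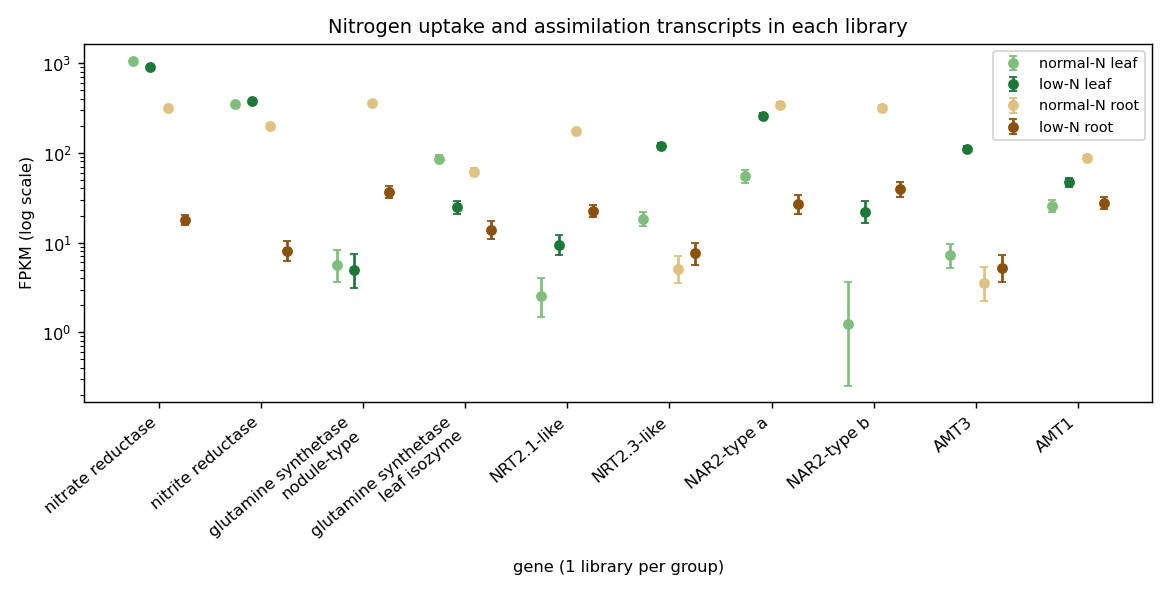
FPKM on a log axis for 10 nitrogen uptake and assimilation genes, 1 point per library, with bars for the 95% Poisson counting interval. Nitrate reductase stood at 314 FPKM in normal-N root and 17.9 FPKM in low-N root, and AMT3 at 7.22 FPKM in normal-N leaf and 109 FPKM in low-N leaf.

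In root, transcripts of nitrate assimilation and most NRT2 and NAR2 transcripts of nitrate uptake were lower under low N. Nitrate reductase (Ma09_g14900), the entry step of nitrate assimilation, was at 314 and 17.9 FPKM, 17.6-fold lower (15.3 to 20.2). Nitrite reductase (Ma09_g14720) was at 199 and 8.11 FPKM, 24.6-fold lower (19.2 to 32.1). A glutamine synthetase of the nodule type (Ma01_g15700) was at 360 and 36.7 FPKM. Of the nitrogen assimilation genes in the authors' deposited table for root, 11 were lower and 0 higher.

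The nitrogen assimilation list had a median log2 change of -2.66 over 12 members, below all 10000 random lists, but 11 of them had been picked for change in root. By BLAST description alone, which leaves out cytochrome b5-like genes found through the KEGG text, 9 of 9 were lower in the authors' deposited table. NADH-dependent glutamate synthase 1 (Ma07_g25920) was 2.33-fold lower (2.18 to 2.49). The NRT2 and NAR2 list had a median of -2.90 over 5 members at percentile 0.025. NRT2.1-like (Ma08_g13030) was at 173 and 22.3 FPKM, 7.73-fold lower (6.55 to 9.18), and the NAR2-type genes Ma06_g13610 and Ma09_g01900 were 12.9-fold (10.1 to 16.7) and 8.06-fold (6.54 to 10.02) lower. NRT2.3-like (Ma04_g06400) was the exception of that list, at 5.10 and 7.57 FPKM. Ammonium transporter 1 member 1-like (Ma11_g15780) was 3.20-fold lower (2.71 to 3.80). Of the NPF family 5 genes were lower and 0 higher in the authors' deposited table, and the median of -0.10 stood at percentile 49.1. LOB factors, a plant-specific family of transcription factors, were lower for 6 of 6 genes in the authors' deposited table, with a median of -2.16 at percentile 0.090. LOB41-like (Ma04_g06820) was at 94.5 and 6.66 FPKM and LOB37-like (Ma04_g14140) at 26.4 and 3.56 FPKM.

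In the authors' deposited table for root, more phenylpropanoid and lignin genes and more defence genes were lower than higher under low N. Phenylpropanoid and lignin genes were lower for 20 genes and higher for 6 in the authors' deposited table, with a median of -1.07 at percentile 0.050. By BLAST description alone the list had 9 lower and 5 higher in the authors' deposited table and stood at percentile 11.95, inside the central 95% of random lists. Trans-cinnamate 4-monooxygenase-like (Ma03_g05400) was at 251 and 32.5 FPKM. Secondary-wall cellulose synthases CesA7 (Ma05_g15620) and CesA4 (Ma09_g05430) were 11.4-fold (9.27 to 14.2) and 10.1-fold (8.05 to 12.9) lower, but the secondary wall list they belong to had 5 genes higher and 7 lower in the authors' deposited table for root, with a median of 0.08 at percentile 82.8 and a mean of -0.52. Defence proteins were lower for 36 genes and higher for 6 in the authors' deposited table, with a median of -0.52 at percentile 0.345 and a mean of -0.79. The class III peroxidase list, which also held 2 L-ascorbate peroxidase 6 genes of another class, went both ways, 19 lower and 14 higher in the authors' deposited table. Its median was -0.89, at percentile 0.15, and its mean -0.12. Peroxidase P7-like genes Ma02_g17270 and Ma06_g00650 were among the most positive changes of root, 34.4-fold (21.0 to 60.7) and 13.3-fold (7.55 to 25.4) higher. Peroxidase 1-like (Ma02_g04930) was at 13.5 and 0 FPKM, at least 19.7-fold lower. Abscisic acid genes were lower for 8 genes and higher for 0 in the authors' deposited table, with a median of -1.35 at percentile 1.48, and the receptor PYL4-like (Ma05_g31850) was at 9.37 and 1.49 FPKM. Metal handling genes, 1 higher and 9 lower in the authors' deposited table, stood at percentile 1.47, with zinc transporter 1 (Ma07_g14980) at 47.3 and 3.75 FPKM. Genes of the root surface and endodermis went both ways, 4 higher and 7 lower in the authors' deposited table, with a median of -1.30 at percentile 0.165 and a mean of -0.61. Among them was dirigent protein 21-like (Ma11_g09770), at 33.0 and 0.89 FPKM.

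At the upper end of the random lists in root stood the list drawn up for vacuolar and cysteine proteases. Its 21 members were mostly other kinds: 13 aspartic proteinases, 3 serine carboxypeptidases, 3 cysteine proteinase inhibitors, 1 cysteine proteinase and 1 vacuolar-processing enzyme. The 3 inhibitors were lower in root. The list had a median of 1.03 over 21 members, above all 10000 random lists, and a mean of 0.44, with 11 genes higher and 4 lower in the authors' deposited table. With 15 members picked for change in root, that percentile is not independent evidence of a direction. An aspartic proteinase, nepenthesin-1 (Ma11_g04120), was 4.79-fold higher (3.84 to 6.04) and ASPARTIC PROTEASE IN GUARD CELL 2-like (Ma07_g16690) 4.10-fold higher (2.94 to 5.84). Cell wall genes went both ways, 31 higher and 28 lower in the authors' deposited table, with a median of 0.16 at percentile 99.7 but a mean of the other sign, -0.04. A xyloglucan endotransglucosylase/hydrolase (Ma08_g19890) was at 1.36 and 19.8 FPKM, 14.5-fold higher (5.96 to 46.1), and a fasciclin-like arabinogalactan protein (Ma02_g10950) at 15.5 and 105 FPKM. The histone and cell cycle list stood at percentile 98.1, and at 92.4 by BLAST description alone. Through the KEGG text it also held other genes, such as GDSL esterases and receptor kinases. Of the 8 genes in the NIN-like list, with a median of 0.92 at percentile 98.8 and a mean of 0.04, 3 were mavicyanin-like, 1 chemocyanin-like and 1 phylloplanin-like, which share only an ending with the name. The other 3 were NLP1-like, and NLP1-like (Ma05_g21510) was 2.63-fold higher (1.83 to 3.85). Carotenoid cleavage dioxygenase 8 (Ma02_g11250), an enzyme of strigolactone synthesis, was at 1.32 and 19.4 FPKM, 14.6-fold higher (7.74 to 31.2).

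Of single genes, non-symbiotic hemoglobin 2-like (Ma02_g10610) had the most negative change in root, at 1039 and 2.89 FPKM, 361-fold lower (166 to 985). Pyruvate decarboxylase 1-like (Ma11_g23090), an enzyme of ethanol fermentation, was at 34.2 and 0.49 FPKM, and 1-aminocyclopropane-1-carboxylate oxidase (Ma05_g09360), which makes ethylene, at 201 and 4.10 FPKM. Root-type ferredoxin (Ma09_g30430), an electron donor, was at 605 and 25.6 FPKM. A salt stress-induced protein (Ma10_g09830) was at 834 and 14.3 FPKM, and the lectin horcolin-like (Ma10_g09820) at 590 and 23.6 FPKM. WD repeat-containing protein 76 (Ma01_g14260) was at 30.5 and 0 FPKM. On the higher side, polyphenol oxidase (Ma08_g09150), which oxidises phenolics, was at 348 and 3391 FPKM, 9.74-fold higher (9.36 to 10.1), and the chitinase hevamine-A-like (Ma08_g33260) at 105 and 1389 FPKM. Primary amine oxidase (Ma01_g13020) was at 0 and 12.1 FPKM, at least 39.2-fold higher by the floor of 3 counts. Squalene epoxidase 3-like (Ma08_g04880) and glu S.griseus protease inhibitor-like (Ma04_g13620) had 0 counts under normal N. By the same floor they were at least 5.82-fold and 4.65-fold higher. YLS3-like (Ma07_g12130) was at 0.40 and 13.0 FPKM.

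By size, 1144 genes were higher and 1690 lower in low-N root among 24476 genes at the filter. Simulated counting noise alone gave a mean of 337 higher and 330 lower genes.

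**Figure D2:**
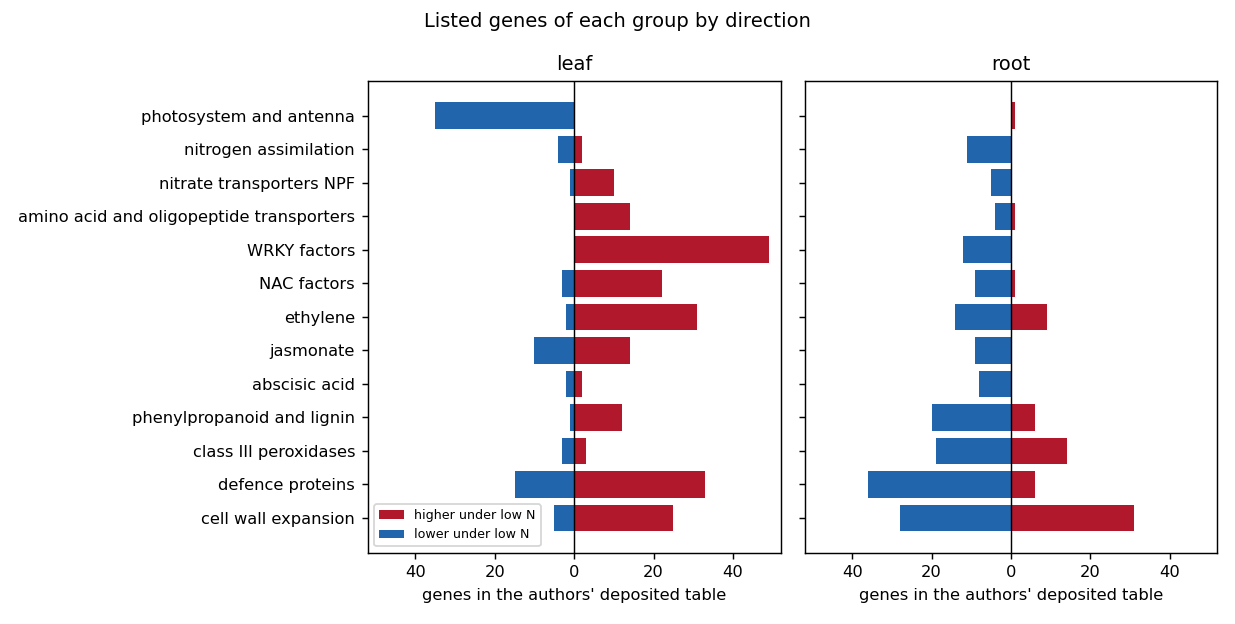
Number of genes of 13 lists in the authors' deposited table for leaf and for root, higher under low N to the right of 0 and lower to the left. WRKY factors had 49 higher in leaf and 12 lower in root, and photosystem and antenna genes 35 lower in leaf.

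The next comparison was between the changes of leaf and root. The nitrate uptake partner NAR2 was higher in low-N leaf and lower in low-N root, at 54.5 and 255 FPKM in leaf against 343 and 26.7 FPKM in root for Ma06_g13610. The second NAR2-type gene (Ma09_g01900) was at 1.24 and 22.1 FPKM in leaf, 17.8-fold higher (5.75 to 88.8), and at 314 and 39.1 FPKM in root. NAC48-like (Ma06_g19100) was 7.67-fold higher in leaf (4.08 to 16.0) and 9.87-fold lower in root (4.27 to 28.0). Polyphenol oxidase (Ma08_g09150) took the other direction, at 25.6 and 0.71 FPKM in leaf. Of the other genes described as polyphenol oxidase, Ma08_g09160 and Ma08_g09170 shared this pattern. In contrast, Ma07_g03540, Ma10_g20510 and Ma08_g34740 were higher in low-N leaf. The last was at 16.1 and 108 FPKM in leaf and at 21.7 and 11.0 FPKM in root. Flavonoid genes leucoanthocyanidin dioxygenase-like (Ma05_g03850) and chalcone synthase 2-like (Ma06_g12370) were 30.9-fold (10.2 to 152) and 52.7-fold (9.06 to 2122) lower in leaf. In root they were 2.21-fold (2.02 to 2.43) and 2.12-fold (1.80 to 2.50) higher. The flavonoid and anthocyanin list they belong to did not share this pattern. For leaf it had 10 genes higher and 7 lower in the authors' deposited table. Its leaf median was 0.92 at percentile 52.9, and its mean 0.02. For root it had 4 higher and 7 lower, with a median of -0.35 at percentile 10.2. Both medians lay inside the range of random lists. Perakine reductase-like (Ma08_g27540) was 16.5-fold lower in leaf and 2.17-fold higher in root. Genes without an informative description met the rule as well: Ma10_g21270 and Ma10_g00800 were higher in leaf and lower in root, and Ma06_g25780 was lower in leaf and higher in root. For Ma10_g00800 and Ma06_g25780, which rest on few counts, the counting intervals included no change in both tissues.

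WRKY factors were lower for 12 genes and higher for 0 in the authors' deposited table for root, against 49 higher and 0 lower in leaf. Over the 49 members measured in root the median was -0.33 at percentile 10.1, inside the central 95% of random lists. WRKY17 (Ma01_g18830) was 5.13-fold higher in leaf (3.75 to 7.14) and 3.19-fold lower in root (2.26 to 4.59), and WRKY9 (Ma07_g20190) 3.98-fold higher (2.52 to 6.51) and 6.49-fold lower (3.75 to 12.04). Small heat shock protein of 18.1 kDa (Ma01_g14490) was lower in both tissues, 8.27-fold in leaf and 13.7-fold in root. Chloroplast copper-zinc superoxide dismutase (Ma10_g07820) was higher in both, 6.09-fold and 3.60-fold. Among 19179 genes at the filter in both tissues, 278 genes had size calls of the same direction and 243 of opposite direction. By direction, 120 were higher in both where independent lists would share 59.8, 158 lower in both against 49.9, 163 higher in leaf and lower in root against 95.8, and 80 the other way against 31.1. Since opposite directions exceeded independence as well, the excess does not show a shared response. The change in leaf and in root had a Pearson correlation of 0.058 and a Spearman correlation of 0.049 across genes, which are not independent replicates. The difference between tissues was not tested.

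Leaf and root were also compared under normal N, as a check of the tissues. The 5 genes named per direction were picked for the largest log2 difference among described genes, and no gene list was compared between the tissues. The RuBisCO small chain (Ma02_g24600) was at 47042 FPKM in leaf and 60.6 FPKM in root, and carbonic anhydrase 2-like (Ma06_g29120) at 7453 and 4.30 FPKM. LHCII type 1 (Ma04_g07920) was at 1259 and 0.29 FPKM, peroxiredoxin Q (Ma05_g16490) at 1539 and 1.09 FPKM, and a non-specific lipid-transfer protein (Ma04_g17200) at 1284 and 0 FPKM. Root held hemoglobin 2-like (Ma02_g10610) at 1039 FPKM against 0.51 FPKM in leaf, peroxidase 60-like (Ma02_g06740) at 764 FPKM against 0, and peroxidase P7-like (Ma02_g17250) at 702 FPKM against 0.26 FPKM. Horcolin-like (Ma10_g09820) at 590 FPKM and TUB8-like (Ma10_g28910) at 582 FPKM had 0 in leaf. By size, 5179 genes were higher in leaf and 10863 higher in root. Of these calls 32.3% were higher in leaf with FPKM as deposited and 42.7% after median-ratio scaling (6639 higher in leaf, 8920 higher in root), which moved the median log2 difference of all genes from -0.63 to -0.26.

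The authors' deposited tables held 2225 genes for leaf, of which 1501 were higher and 724 lower under low N, and 1354 for root, of which 534 were higher and 820 lower. Of the leaf genes, 1413 of those higher and 679 of those lower were also called by size, and of the root genes 467 and 766. Size calls that were in neither direction of the authors' deposited table numbered 1899 in leaf and 1601 in root, with a median level of 5.00 and 4.87 FPKM in the higher library, against 29.5 and 23.8 FPKM for genes in it. The tables of both tissues shared 183 genes: 38 were higher in both, 58 lower in both, 63 higher in leaf and lower in root, and 24 lower in leaf and higher in root. Independent lists drawn from the 27139 genes seen in both tissues would share 29.5, 21.9, 45.4 and 14.2 genes in that order. That gene number includes many weaker than most genes of the authors' deposited tables, which lowers the expected counts. The shared counts were above them in opposite directions as well, so the excess does not show a shared response.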

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

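The tests in this part were chosen after the results they bear on were seen. Some genes went in opposite directions in leaf and root, and some lists differed between the tissues in the share of their genes that were higher. Neither difference was tested, since each group had 1 library. The leaf minus root difference in log2 change was 6.34 for the NAR2-type gene Ma09_g01900 and 5.84 for Ma06_g13610. It was 6.60 for Ma10_g21270, which has no informative description, 5.22 for NAC48-like (Ma06_g19100) and 5.04 for Ma10_g00800. In the other direction it was -7.24 for polyphenol oxidase (Ma08_g09150), -5.48 for Ma06_g25780, -4.84 for leucoanthocyanidin dioxygenase-like (Ma05_g03850), -4.37 for chalcone synthase 2-like (Ma06_g12370) and -4.28 for perakine reductase-like (Ma08_g27540). As given above, Ma10_g00800 and Ma06_g25780 rest on few counts, and their counting intervals included no change in both tissues. As the share of a list's genes in the authors' deposited tables that were higher under low N, leaf exceeded root by 100 percentage points for NRT2 and NAR2 genes and for WRKY factors. The excess was 90.9 points for NPF genes, 80 points for amino acid and oligopeptide transporters and 78 points for NAC factors. Over all genes of those tables the share was 67.5% in leaf and 39.4% in root. In root the shares rest on 4 NRT2 and NAR2 genes, 5 NPF genes, 5 amino acid transporters, 10 NAC factors and 12 WRKY factors. Over all members measured in root the medians of the NPF, amino acid transporter, NAC and WRKY lists were -0.10, -0.011, -0.19 and -0.33, inside the central 95% of random lists. Members absent from the root table had been picked in leaf, which was so for most WRKY and NAC genes. The medians therefore describe the lists as drawn and cannot settle whether the families stood apart in root.

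Of the 4 NRT2 and NAR2 genes higher in low-N leaf in the authors' deposited table, 3 were lower in low-N root, and NRT2.3-like (Ma04_g06400) was not. Root RNA carried into the low-N leaf library would have brought other root transcripts with it. Among 24 genes abundant in both root libraries and under 1 FPKM in normal-N leaf, the highest level in low-N leaf was 0.581% of that in low-N root, while the higher level of the 4 genes in low-N leaf needs at least 31.0%. The scalings were too small to account for the pattern: under them the lowest log2 change in leaf of the 4 genes was 1.41, and the highest in root of the 3 was -2.80. A difference between the tissues in how these genes answer low nitrogen stays open, as an untested explanation.

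Bowman-Birk inhibitors, lectins, 9S-lipoxygenases, polyphenol oxidases, ribonucleases, a glutelin and a patatin-like protein that were lower in low-N leaf in the authors' deposited table, 23 genes picked for that pattern, were also expressed in root. Their level in normal-N leaf had a median of 6.36% of that in normal-N root, with a range from 1.28% to 226%, and 1 gene was above its root level. Root RNA in the normal-N leaf library would give other root-abundant genes a like share, but over 75 of those that were low in low-N leaf the median was 0.341%, and 73 lay below 6.36%. The scalings moved the median leaf change of all genes only from 0.12 to values between -0.08 and 0.21, too little to account for a median of the 23 genes that was -3.03 or lower under each. The aboveground samples held pseudostem as well as leaf, and a different share of pseudostem in each library was not tested; a response to low nitrogen is also open.

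The cyclin-dependent kinase regulatory subunit gene Ma02_g13600 appeared to switch on in low-N leaf, with a log2 change of 3.79. Its copy Ma02_g13560 has the same coding length and equal FPKM, within 0.5%, in the other 3 libraries. Summed over both copies the log2 change was -0.85, so assignment of shared reads to a single copy is a candidate explanation for the apparent switch. The same search over the 58 cases of a gene in the authors' deposited tables at 0 in 1 library of its pair found such a copy for 1, so shared reads of this kind do not account for most of them.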

How the results depend on the processing

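Within a tissue no paired analysis was possible, because the groups had 1 library each and so shared fewer than 2 replicate numbers. No library could be left out. A low-N effect over both tissues, blocked on tissue, was not run. Counts moved by over 1.5 times as follows, with the higher count before the lower one. With a pseudocount of 5, leaf had 1026 and 593 genes and root 341 and 680, with 74 of the same and 45 of opposite direction in both tissues. With a pseudocount of 0.1, 373 genes were of opposite direction. With a filter of 10 FPKM, leaf had 1388 and 778, root 491 and 852, with 96 of the same and 73 of opposite direction. With a size limit of 2, leaf had 426 and 272, root 185 and 393, leaf against root 2806 and 5910, with 33 of the same and 25 of opposite direction. These settings admit fewer or more genes by construction. After median-ratio scaling, which moved the median log2 change of all leaf genes from 0.12 to -0.08, 2234 genes were lower in leaf. With an authors' log2 ratio of at least 2, their deposited lists held 424 higher and 195 lower in leaf, and 128 and 344 in root. The phosphate response list in leaf had a median of 0.53 and took the other sign with members of at least 5 FPKM (-0.95), with the mean over members (-0.19) and by BLAST description only (-0.18, chosen after seeing the data). The histone and cell cycle list in leaf went from 1.04 to -0.91 by BLAST description only, which keeps 34 of its 68 genes. The others, such as GDSL esterases and receptor kinases, were found through the KEGG text. With the change of members its genes in the authors' deposited table for leaf went from 29 higher and 19 lower to 9 and 11. With the mean in place of the median, 30 of 69 list values moved by at least 0.25 without such a change of sign. So did 22 with a pseudocount of 5, 16 without a filter on members and 12 with members of at least 5 FPKM. Another 9 did by BLAST description only and 5 with a pseudocount of 0.1. Lists outside the central 95% of random lists numbered 9 in leaf, and 6 to 13 under the alternatives. In root they numbered 13, and 9 to 13 under the alternatives. Among the medians, no other one of at least 0.5 in size changed sign; smaller ones did in places. For named genes, picked for large changes, a change of sign under the pseudocounts or scalings was hardly possible. Of their values under those settings, 716 stayed within the counting interval and 44 did not. Depth limited weak genes most: 3 counts correspond to 0.680 to 0.724 FPKM at 1 kb.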

Other observations

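The test in this part was chosen after the result was seen. Phosphate genes of leaf went both ways, 8 higher and 8 lower in the authors' deposited table. SPX domain protein 1-like (Ma04_g37210) was at 71.0 and 6.41 FPKM, 11.1-fold lower (7.25 to 17.9), while phosphate transporter 1-10 (Ma03_g03540) was at 5.08 and 24.6 FPKM, 4.82-fold higher (3.34 to 7.16). A metallothionein-like gene (Ma06_g27920) was at 6215 and 2282 FPKM in leaf and at 101 and 339 FPKM in root. The autophagy gene ATG13-like (Ma04_g33620) was 2.63-fold higher in leaf (1.65 to 4.30). In root, sucrose synthase 1-like (Ma07_g21330) was at 338 and 36.0 FPKM, tonoplast aquaporin TIP2-1 (Ma11_g19380) at 75.1 and 460 FPKM, and gibberellin-regulated protein 6-like (Ma07_g19330) at 200 and 1088 FPKM.

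WD repeat-containing protein 76 (Ma01_g14260), with a coding length of 144 nt, had 15 counts in each normal-N library and 0 in each low-N library. It was 1 of 2 genes at 5 FPKM or more in both normal-N libraries and at 0 in both low-N libraries; the other was Ma08_g24750, with 3 and 2 counts, and 1 gene (mito8_g00040), with 1 count in each low-N library, had the opposite pattern. Both were chosen after their values were seen.

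A hypothesis from the leaf values was that transcripts of vegetative storage type (lectins, Bowman-Birk inhibitors, 9S-lipoxygenases, patatin-like proteins, ribonucleases, polyphenol oxidases and glutelins) may be lower as a group in low-N leaf. The group was drawn up after the values were seen. Its median log2 change over 63 members was 0.94, at percentile 24.3 of matched random lists, so the group as drawn did not stand apart. The search term lectin had also caught lectin receptor kinases, and 29 of the 66 genes found had kinase in their description or KEGG text. Leaving kinases out, a choice made only after that result, gave a median of -1.50 over 35 members, below all 10000 random lists, but the narrowed group was shaped by the same values and tests nothing; it would need other plants.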
